A study of Mus musculus with 15 samples.

How the data were processed

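The samples were 15 mouse alveolar macrophage total RNAs, each hybridised on a spotted 2-colour oligonucleotide array with a common reference, labelled as one of macrophages, in the first channel. Groups were taken from the labels: 5 wild type, 5 beta6 null and 5 beta6 null with TGFb1. No label pairs samples across groups, and replicate numbers only name a sample.

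The deposited values are 1 log ratio per probe and array, treated here as log2. Per the file headers and the labels no scanner, dye, background correction or normalization step is named, so what the authors did to make the deposited log2 ratios is not given in the sources used here. The values themselves show that the median of each array lay within 0.05 of 0, so the arrays appear centred, and that spots without a value had been taken out. The base of the logarithm and the direction of the ratio stay unknown: base 2 was taken because values as large as 9.49 would on a base of 10 exceed what a 16-bit scanner can record, and sample over reference because the reference is the first channel and because of Mmp12. If the base were another, every fold would change, and no sign or test would.

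The SD of the values ran from 0.841 to 2.01 between arrays, and 742 to 5610 probes of an array had no value. Wild type replicate 2 and beta6 null replicate 1 had the widest values (SD 2.01 and 2.00) and the most missing ones (5511 and 5610). Arrays correlated with each other at r = 0.194 to 0.576 over probes, with a median of 0.400 within and 0.359 between groups. The medians of the deposited values lay between -0.047 and 0.029.

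Of 17225 probes, 30 were left out, taken as control spots from their names. Of the other 17195, 13972 carried 1 gene symbol in the platform annotation, 13 carried several and 3210 were not listed there. Of these, 13869 symbols were looked up by Entrez ID in a RefSeq gene table of the assembly GRCm38.p6, which was used for names and the order of genes only. Probes of 1 gene were averaged (988 genes had more than 1), and every other probe stood for itself. Among called genes with several probes, the probes of Nrip1 went opposite ways.

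Each array was centred on its median, and features with values on at least 3 arrays of every group were kept (13273, of which 10811 have a gene symbol; 6592 features had values on all 15 arrays). A linear model with 3 group means was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Errors of differences are standard errors of that fit, and errors of group means are SDs over arrays. A difference is always the first named group minus the second. For Mmp12 an exact two-sided permutation test was added.

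Before the data were examined, 28 gene lists were fixed, of cell types, pathways and complexes, with markers of the other cells that a lavage or lung sample could hold. They were tested with camera at its preset correlation of 0.01, run on the moderated statistics of all features, with adjustment over the 28 lists. Beside it stand camera with an estimated correlation and fry, which need complete data and were run on the members measured on all 15 arrays, so their members differ. Counts of members past the threshold are given over all features and adjusted over the list alone. These 2 tests were run on 26 of the 28 lists, those with at least 5 such members, and the other 2 were not tested by them. Of the 26, 0 passed camera with an estimated correlation in each comparison. By fry, 4 lists passed in beta6 null against wild type, 8 in the TGFb1 group against beta6 null and 0 against wild type.

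The genes named were fixed by rule before the data were examined. The rule took the 10 largest rises and the 10 largest falls among features that passed, with 1 symbol and values on at least 4 of 5 arrays of both groups, or the 5 smallest p in each direction where none passed. It added up to 4 members of each list that passed or held at least 2 calls, and 8 genes of the pathway (Mmp12, Spp1, Tgfb1, Itgb6, Itgb5, Itgav, Pparg and Ctsk). Spp1 was not analysed here, since no probe is named for it. The rule took 122 genes. The text describes 72 of them, a choice made after their values were seen, as was the choice of the genes plotted. Xist, Eif2s3y, Kdm5d, S100a8, Cd302, Cytip and Stard4 fall outside the rule and were also chosen after their values were seen.

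The steps were tested on simulated data with the same arrays and missing values. Of 50 genes changed by 1, 2, 3 and 4 log2 units in beta6 null against wild type, 8%, 38%, 60% and 90% were recovered, with 6 unchanged genes called. For the TGFb1 group against beta6 null 8%, 54%, 66% and 84% were recovered, with 5 unchanged genes called. In the simulated TGFb1 group against wild type, where nothing was changed, 0 genes were called. A list of 30 genes shifted by 1 was called and 0 of 27 random lists were. The simulated genes varied independently of each other, while the estimated correlation within a real list reached 0.40. The run therefore does not test false calls of lists whose members vary together.

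Alternatives listed before the data were examined were values as deposited, quantile normalization, other limits on missing values, single probes, fits of 10 arrays, robust eBayes, array weights, the last number of the array titles as a block, leaving out the 2 arrays whose title numbers lie apart, other thresholds, and leaving out each array in turn. After the arrays had been seen, 3 were added: equal spread of all arrays, leaving out the 2 widest arrays, and the level of Xist as a covariate.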

Results

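RNA of alveolar macrophages, the resident phagocytes of the lung airspaces, was measured on 15 spotted 2-colour oligonucleotide arrays. Each array set 1 sample of mouse macrophage total RNA against a common reference RNA. The samples formed 3 groups of 5: wild type mice, mice deficient in the integrin beta6 subunit (beta6 null), and beta6 null with TGFb1. The last group was labelled b6-/-TGFb+/+Dox and read as beta6 null mice with a TGFb1 transgene. All mice had received doxycycline, an antibiotic used to switch on inducible transgenes. The integrin alphavbeta6 sits on lung epithelium and activates latent TGFb, a growth factor that restrains macrophages. The design asks what changes in macrophages without it, and what TGFb1 changes in the beta6 null. Wild type mice with TGFb1 were not measured, so a restoration is not separated from an effect of added TGFb1. The number of values per array was 11714 to 16131 in wild type, 11615 to 16483 in beta6 null and 13093 to 16310 in the TGFb1 group, out of 17225 probes. The number of arrays limits the precision. The labels do not say that the arrays hold separate animals, so p-values measure the spread between these samples, which may be technical.

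The gene disrupted by design, Itgb6, was read by 2 probes. The first gave a value on 1 wild type array (0.61), 2 beta6 null arrays (0.96 and 1.54) and 3 TGFb1 arrays (0.75, 0.94 and 2.88). The second averaged -0.04 ± 0.20 (SD, n = 4) in wild type, 0.22 ± 0.20 (n = 5) in beta6 null and -0.46 ± 0.43 (n = 5) with TGFb1. These are log2 ratios taken as sample over reference. That direction is called likely, from the order of the channels and from Mmp12, which is known for rising in macrophages of this mouse. Neither the files nor the labels state the direction or the base of the logarithm, and were the ratio inverted, every sign given here would turn. Itgb6 belongs to epithelium, and where its probes lie relative to the deleted part is not known, so these values do not check the labels. Averaged over its probes, Itgb6 did not pass between beta6 null and wild type (difference 0.39, SE 0.40, adjusted p = 0.734). The first probe read higher and was missing on most arrays, so this average also depends on which spots had a value. The Tgfb1 probe gave -0.93 ± 2.18 (SD, n = 5) in wild type, -0.68 ± 1.60 in beta6 null and -0.69 ± 0.87 with TGFb1. The differences of Tgfb1, of Itgav (0.50 in beta6 null, SE 0.47) and of Itgb5 (1.73 in beta6 null, SE 0.89) did not pass in any comparison.

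Mmp12, macrophage elastase, stood 19.8-fold higher in beta6 null than in wild type macrophages and lay between the 2 levels with TGFb1. Mmp12 also helped to choose the direction of the ratio, so the sign of its change is not separate evidence. Its log2 ratio was 0.26 ± 0.22 (SD, n = 4, 1 array without a value) in wild type, 4.57 ± 0.82 (n = 5) in beta6 null and 2.26 ± 0.61 (n = 5) with TGFb1. The rise in beta6 null was 4.31 (SE 0.42, adjusted p = 1.8e-04), and 4.07 without a call with the Xist level as a covariate (adjusted p = 0.110, and 3.69e-05 to 0.110 over all alternatives). With TGFb1 the level fell by 2.31 (SE 0.40, adjusted p = 0.020). All 5 beta6 null arrays lay above all arrays of both other groups. The TGFb1 arrays, at 1.365 to 2.695, lay above the wild type arrays, at 0.03 to 0.54. That difference of 1.997 (SE 0.42) did not pass over all genes (adjusted p = 0.578), while the exact two-sided permutation test of Mmp12 by itself gave p = 0.0159 (0.0159 after adjustment over the 3 comparisons). The exact permutation p of the other 2 comparisons was 0.00794, the smallest that 4 against 5 or 5 against 5 arrays can give, and 0.0119 after adjustment. The call of the fall with TGFb1 ended without beta6 null replicate 2 (adjusted p = 0.0543), without TGFb1 replicate 4 (0.0743), under quantile normalization (0.0748), without the 2 arrays numbered apart (0.0619), with the Xist level as a covariate (0.517) and with the spread of the arrays made equal (0.268). The fall was then -2.25, -2.22, -2.05, -2.20, -2.09 and, with equal spread, -1.22. Over all its alternatives, the adjusted p of that fall ran from 0.00496 to 0.517.

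**Figure D1:**
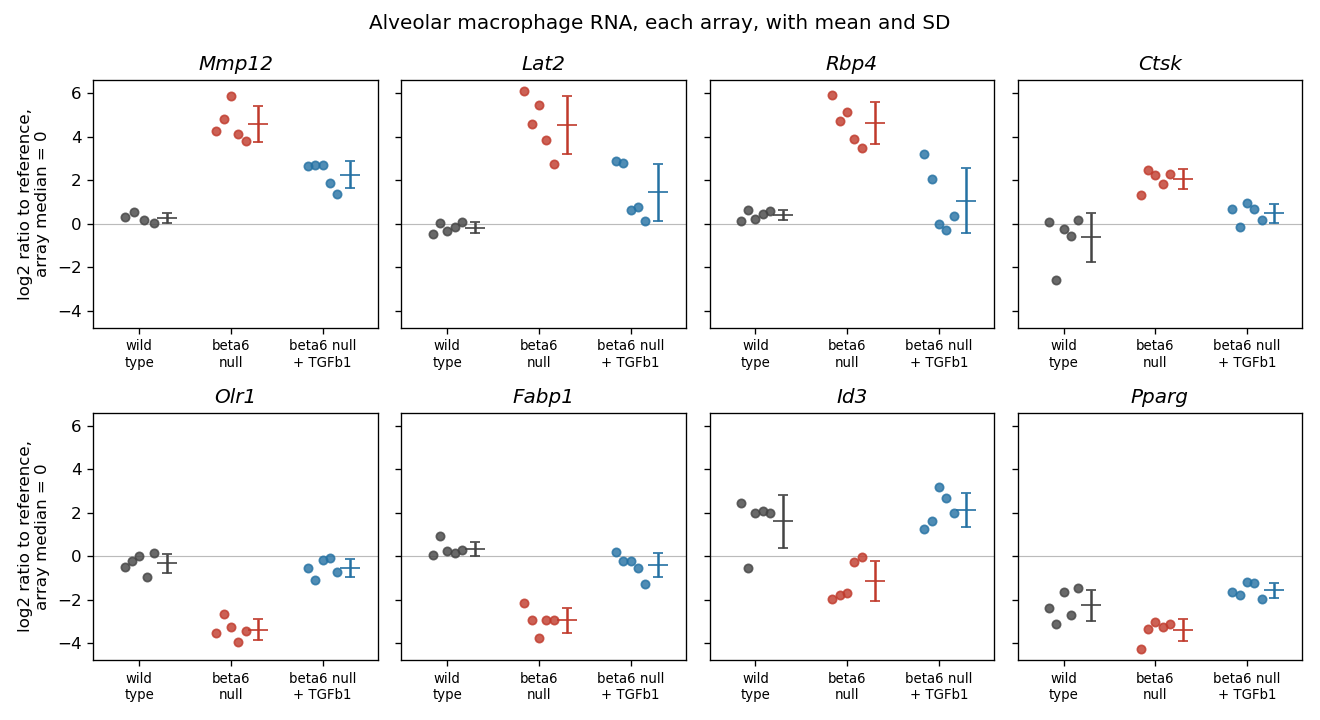
Log2 ratio to the reference, with each array's median set to 0 (vertical axis), of 8 genes in wild type, beta6 null and beta6 null with TGFb1. Each point is 1 array, spread sideways only to be seen, and the bar beside the points gives the mean and SD. Mmp12 averaged 0.26, 4.57 and 2.26 in the 3 groups, and Olr1 -0.31, -3.37 and -0.53.

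In beta6 null against wild type macrophages, 126 of 13273 features changed, 48 higher and 78 lower. Among genes with values on at least 4 arrays of both groups, the largest rises beside Mmp12 were those of Lat2, an adaptor of immune receptor signalling (26.3-fold, adjusted p = 0.00144), Rbp4, the plasma carrier of retinol (18.6-fold, adjusted p = 0.00266), Marcks, a substrate of protein kinase C (13.6-fold), Cd93 (12.7-fold), Dpp4, a cell-surface dipeptidase (11.8-fold), Pmp22 (11.4-fold), Plbd1 (11.3-fold), the lectin Clec10a (11.04-fold) and Wfdc18 (10.4-fold). The largest falls were those of Flt1, a receptor of vascular endothelial growth factor (-4.16, SE 0.54, adjusted p = 0.00117), Wwtr1, a coactivator of the Hippo pathway (-3.40, SE 0.67, adjusted p = 0.0401), Tpra1 (-3.33), Desi1 (-3.28), the transcription factor Prdm1 (-3.28), Fabp1 (-3.27), Oas3 (-3.19), Olr1 (-3.06) and the transcription factor Egr2 (-2.95). Xist, the RNA of the inactive X chromosome in females, was higher too: it averaged -0.40 ± 1.48 (SD, n = 5) in beta6 null, with arrays from -2.46 to 0.88, against -3.10 ± 0.71 (n = 5) in wild type. Xist was singled out after its values were seen. With its level on each array as a covariate, also chosen then, 0 genes passed by limma, and 117 of the called features had an unadjusted p under 0.05. The differences of the called features were then a median of 0.973 of those without it, and their median SE was 0.583 in place of 0.359.

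Genes of alveolar macrophage identity were lower in beta6 null. Of 31 measured members 6 fell, 1 rose and 24 did not pass, and adjusted over the list alone 13 fell and 2 rose (camera adjusted p = 1.55e-06, but adjusted p = 0.176 with an estimated correlation). The members that fell were Olr1, a receptor of oxidised lipoprotein, Fabp1, a fatty acid-binding protein, Flt1, the cytokine Il18 (-2.12, SE 0.28), the keratin Krt19 and the lipid droplet protein Cidec (-1.35, SE 0.25). Flt1 is also on the list of fibroblast and endothelium markers and Krt19 on that of lung epithelium. The one that rose was Fabp5 (2.10, SE 0.23), another fatty acid-binding protein. Beside these, dendritic cell and monocyte markers were higher as a list (camera adjusted p = 0.0225, correlation not estimated). Pparg, the nuclear receptor that sets up this cell type, was at -1.14 (SE 0.36, adjusted p = 0.191) and did not pass. Among 34 genes of lipid uptake, storage and efflux, Olr1, Cidec and Scarb1 (-1.18, SE 0.26) fell and Fabp5 rose (camera adjusted p = 0.380). Among 57 genes of proliferation, 1 passed, Rrm2, a subunit of ribonucleotide reductase (-1.33, SE 0.28), and 3 fell when adjusted over the list alone. The list as a whole lay lower (median -0.49, 45 of 57 members below 0, camera adjusted p = 5.5e-05, and adjusted p = 0.221 with an estimated correlation).

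Targets of TGFb signalling fell in part. Of 34 members, 4 fell: Skil (-1.86, SE 0.31) and Klf10 (-1.07, SE 0.22), both induced by TGFb, Id3 (-2.74, SE 0.59), an inhibitor of basic helix-loop-helix factors, and Eng (-1.97, SE 0.43), a coreceptor. Adjusted over the list alone 8 fell and 1 rose, and the list as a whole did not pass camera (adjusted p = 0.135) but did pass fry, lower, on the 20 members measured on all 15 arrays (adjusted p = 0.00171).

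Chemokines and their receptors were higher in beta6 null as a list of 35 (camera adjusted p = 0.00554, and adjusted p = 0.200 with an estimated correlation), of which 2 rose, also when adjusted over the list alone: Ccl9 (2.88, SE 0.43) and Ccl5 (2.11, SE 0.35), both attractants of leukocytes. Dendritic cell and monocyte markers were higher as a list of 15 (camera adjusted p = 0.0225), with 12 members above 0. The one that passed over all genes, the endocytic receptor Ly75, fell (-2.72, SE 0.36), and adjusted over the list alone 3 rose and 1 fell. Without the 2 widest arrays this list no longer passed (camera adjusted p = 0.0807), and with 4 members on all 15 arrays its correlation was not estimated. In MHC class II presentation 2 of 16 members rose, H2-Ea (2.50, SE 0.44) and H2-Aa (1.82, SE 0.40), and 4 when adjusted over the list alone (camera adjusted p = 0.0616). Among 35 genes of complement, Fc and pattern receptors, the anaphylatoxin receptor C3ar1 (3.16, SE 0.50) and Gas6 (2.88, SE 0.61), a bridge to dying cells, rose, while Tlr2 (-2.53, SE 0.36) and complement factor Cfb (-1.51, SE 0.27) fell (camera adjusted p = 0.380; 4 rose and 4 fell when adjusted over the list alone). Of 40 cathepsin and lysosome genes, the proteases Ctsk (2.68, SE 0.46) and Ctsb (1.58, SE 0.35) rose, also when adjusted over the list alone (camera adjusted p = 0.107). In the metalloproteinase list of 25, Mmp12 was the 1 member that passed, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0648). Classical activation had Ccl5 higher and Il18 lower among 31 members, with Tnf at -2.06 (SE 0.50, adjusted p = 0.083), and alternative activation had Clec10a higher and Egr2 lower among 24. Neither list passed (camera adjusted p = 0.302 and 0.304).

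No other list of markers of lung cells passed camera in beta6 null. Camera placed the fibroblast and endothelium list lower and the other lists of this paragraph higher. The median member of the neutrophil and erythroid lists lay below 0 all the same (-0.124 and -0.067). The single members that passed went both ways. Among 37 lung epithelium markers, surfactant protein gene Sftpc rose (2.18, SE 0.47) and Epcam (-2.34, SE 0.42) and Krt19 (-2.01, SE 0.40) fell. Among 15 B and plasma cell markers, Blnk rose (2.87, SE 0.61) and Prdm1 fell. Of 20 fibroblast and endothelium markers, Flt1 and Eng fell. The neutrophil list of 13 had 1 call, S100a8, higher at adjusted p = 0.00148, a calgranulin that falls outside the rule for named genes and was singled out after its value was seen. No member passed among 23 T and NK cell markers, 16 eosinophil, basophil and mast cell markers or 9 erythroid markers. The camera adjusted p of these 7 lists ran from 0.107 to 0.436.

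Beside Mmp12, 43 genes that the rule names passed in beta6 null against wild type. Of these, 43 kept their sign in all 23 alternatives, and 0 kept their call in all 23, since none passed with the Xist level as a covariate. Of the 43, 27 passed in each of the 15 fits that left out 1 array. Dpp4, Pmp22, Wwtr1, Ctsb, Klf10, Id3, Eng, Cidec, Scarb1, Rrm2, H2-Ea, H2-Aa, Gas6, Blnk, Krt19 and Sftpc lost their call in at least 1 of them, with a highest adjusted p of 0.149. The count of 126 fell to 81, 68, 80 and 64 without wild type replicate 1, 3, 4 and 5, and to 72 without beta6 null replicate 2. It was 41 with the 10 arrays of the 2 groups alone, 64 with the title suffix as a block, 78 without the 2 arrays numbered apart and 422 with array weights. It was 190 without wild type replicate 2 and beta6 null replicate 1, the arrays with the widest values and fewest measured probes (72 higher, 118 lower). The split of 48 higher to 78 lower became 40 to 36 under quantile normalization and 30 to 31 with the spread of the arrays made equal.

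**Figure D2:**
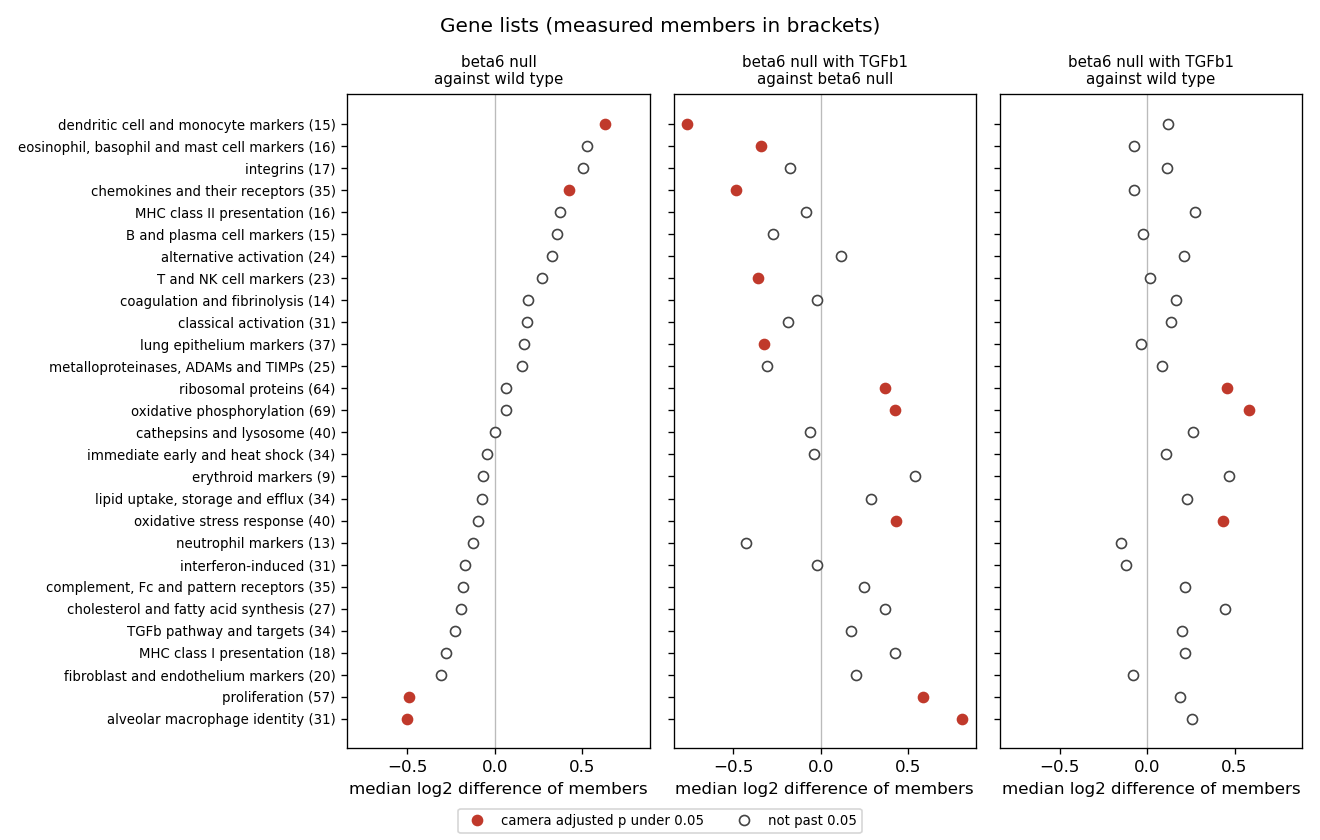
Median log2 difference over the measured members of each of 28 gene lists (horizontal axis), in each of the 3 comparisons, with the number of members in brackets. Filled points passed camera with its preset correlation (4, 10 and 3 lists), and with an estimated correlation 0 of the 26 lists with enough complete members passed in each comparison, the dendritic cell and monocyte list not being among the 26.

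With TGFb1, 94 features differed from beta6 null macrophages, 77 higher and 17 lower. Among genes with values on at least 4 arrays of both groups, the largest rises were those of Id3 (9.7-fold), Olr1 (7.1-fold, adjusted p = 0.00114), Desi1 (7.0-fold), the stress kinase Eif2ak4 (6.6-fold), the glycolytic enzyme Aldoc (6.6-fold), the calcium-binding protein Gca (6.1-fold), A930007I19Rik (5.8-fold), Fabp1 (5.8-fold), Tpra1 (5.7-fold) and Oas3 (5.6-fold). The largest falls were those of Rbp4 (-3.57, SE 0.62, adjusted p = 0.0192), Plbd1 (-3.49, SE 0.43, adjusted p = 0.00213), Dpp4 (-3.25, SE 0.62), Aif1, an actin-binding macrophage protein (-3.20, SE 0.62), Lat2 (-3.10, SE 0.64), the histidine-degrading enzyme Hal (-2.64, SE 0.40), Marcks (-2.53, SE 0.51), Wfdc18 (-2.46, SE 0.39), Igf2r (-2.44, SE 0.43) and Mmp12. Xist was at -3.07 ± 0.49 (SD, n = 5) with TGFb1, against -0.40 in beta6 null, and with its level as a covariate 0 genes passed by limma here too, with 91 of the 94 at an unadjusted p under 0.05. The differences were then a median of 0.970 of those without it, and the median SE was 0.543 in place of 0.336.

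Alveolar macrophage identity genes were higher with TGFb1 than in beta6 null: 5 of 31 rose, 1 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.0e-06, but adjusted p = 0.0857 with an estimated correlation). Olr1, Il18 (2.46, SE 0.28), Fabp1, Krt19 (2.37, SE 0.40) and Pparg (1.84, SE 0.35) rose and Fabp5 (-1.17, SE 0.23) fell, while dendritic cell and monocyte markers were lower as a list (camera adjusted p = 0.00928, correlation not estimated). In the TGFb list 5 of 34 rose: Klf10 (1.73, SE 0.22), Id3 (3.27, SE 0.59), Id1 (2.02, SE 0.39), a partner of Id3 in function, Skil (1.47, SE 0.31) and the receptor kinase Axl (1.23, SE 0.25). Itgae, the integrin alphaE of epithelial lymphocytes and dendritic cells, fell (-3.89, SE 0.73, 3 and 5 arrays), and the list as a whole did not pass camera (adjusted p = 0.0555; 6 rose and 1 fell when adjusted over the list alone) but did pass fry, higher, on its 20 complete members (adjusted p = 8.94e-05). Proliferation genes were higher (camera adjusted p = 2.2e-04, and adjusted p = 0.0857 with an estimated correlation). The cyclin Ccnd2 (2.004, SE 0.40) and the mitotic kinase Cdk1 (1.52, SE 0.33) rose over all genes, and 13 of 57 when adjusted over the list alone. Cfb (1.80, SE 0.27), Tlr2 (1.80, SE 0.36) and Axl rose among complement, Fc and pattern receptors, a list that did not pass (camera adjusted p = 0.323; 5 rose and 2 fell when adjusted over the list alone).

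Chemokines and their receptors were lower with TGFb1 than in beta6 null as a list (camera adjusted p = 7.1e-05, and adjusted p = 0.0857 with an estimated correlation). None passed over all genes, with Ccl5 at -1.29 (SE 0.35, adjusted p = 0.104) and Ccl9 at -1.53 (SE 0.43, adjusted p = 0.106), and 3 of 35 fell when adjusted over the list alone. Ctsk was at -1.57 (SE 0.46, adjusted p = 0.122). Dendritic cell and monocyte markers were lower (camera adjusted p = 0.00928), with Itgae the 1 of 15 that passed; 1 rose and 2 fell when adjusted over the list alone, and its correlation was not estimated. The lung epithelium list was called lower (camera adjusted p = 0.0464, and adjusted p = 0.775 with an estimated correlation), with 25 of 37 members below 0, although the 2 members that passed, over all genes and over the list alone, were Krt19 and Epcam (1.98, SE 0.42), which rose. T and NK cell markers (23, median -0.36) and eosinophil, basophil and mast cell markers (16, median -0.345) were also called lower at camera adjusted p = 0.0464. No member passed over all genes or over either list alone, and adjusted p = 0.505 and 0.650 with an estimated correlation. The eosinophil call ended without the 2 widest arrays (camera adjusted p = 0.142).

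Genes of oxidative phosphorylation, the respiratory chain of mitochondria, were higher with TGFb1 than in beta6 null (53 of 69 above 0, median 0.42, camera adjusted p = 9.96e-04, and adjusted p = 0.570 with an estimated correlation). Of these Atp5pb, a subunit of ATP synthase, passed (1.62, SE 0.34), and 11 rose when adjusted over the list alone. Ribosomal protein genes were higher as a list (49 of 64 above 0, median 0.37, camera adjusted p = 0.0249, and adjusted p = 0.613 with an estimated correlation), with none past the threshold over all genes or over the list alone and Rpl9 at 1.35 (SE 0.34, adjusted p = 0.0843). Oxidative stress genes were called higher (32 of 40 above 0, camera adjusted p = 0.0464, and adjusted p = 0.570 with an estimated correlation). None of them passed over all genes, with Hmox1, heme oxygenase, at 1.17 (SE 0.29, adjusted p = 0.073), and 5 rose when adjusted over the list alone. That call ended under quantile normalization (camera adjusted p = 0.139), with equal spread (0.228) and without the 2 widest arrays (0.0916). The median difference of all features was 0.12 in this comparison.

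Beside Mmp12, 33 genes that the rule names passed in this comparison. Of these, 33 kept their sign in every alternative that gave them a value (23, but 20 for Igf2r and 19 for Itgae). In all alternatives together 0 of the 33 kept their call, since none passed with the Xist level as a covariate. Of the 33, 14 passed in each fit that left out 1 array (15, but 12 for Igf2r and Itgae). Id3, Eif2ak4, Rbp4, Dpp4, Aif1, Lat2, Marcks, Igf2r, Id1, Itgae, Krt19, Pparg, Fabp5, Ccnd2, Cdk1, Tlr2, Axl, Epcam and Atp5pb lost their call in at least 1, with a highest adjusted p of 0.142. The count of 94 became 318 without wild type replicate 2, 38 and 52 without beta6 null replicate 2 and 4, and 40, 49, 24 and 23 without TGFb1 replicate 1, 2, 3 and 4. It was 43 with the title suffix as a block, 30 without the 2 arrays numbered apart, 220 among features on all 15 arrays and 620 with array weights. It was 321 without the 2 widest arrays (259 higher, 62 lower), 11 with the spread of the arrays made equal and 15 under quantile normalization, where the split was 8 higher to 7 lower.

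Between macrophages of the TGFb1 group and wild type, 0 of 13273 features passed by limma (833 at an unadjusted p under 0.05, where 664 are given by chance). This does not show that the groups are alike. In the simulated data, 8% of changes of 1 log2 unit were recovered in each of the other 2 comparisons. Of changes of 2 units, 38% and 54% were recovered, and no change was simulated for this comparison. The genes with the smallest p, which did not pass, were Egr2 (-1.76, SE 0.32, adjusted p = 0.319), Flt1 (-2.95, SE 0.54, adjusted p = 0.319), Noct (-1.14, SE 0.24), Rrm2 (-1.26, SE 0.28) and Tnfsf13b, a survival factor of B cells (-1.28, SE 0.31), on the lower side. On the higher side they were Aass (1.93, SE 0.37, adjusted p = 0.428), Ccdc59 (1.67, SE 0.33), Mmp12, the growth factor Igf1 (2.09, SE 0.45) and Id2 (1.65, SE 0.38). Flt1 passed in 3 alternatives: with array weights (-2.63, adjusted p = 0.001335), without beta6 null replicate 1 (adjusted p = 0.0453) and in a fit of the 10 arrays of the 2 groups (adjusted p = 0.0401). Without TGFb1 replicate 5 an unnamed probe passed instead, so that each of these fits held 1 call. Over the 3 groups together, 112 features differed by the moderated F test, and 222 and 73 without wild type replicate 2 and 3, 56 without beta6 null replicate 2, and 70 and 68 without TGFb1 replicate 3 and 4.

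As lists, oxidative phosphorylation (59 of 69 above 0, median 0.58, camera adjusted p = 1.19e-08), ribosomal proteins (56 of 64 above 0, median 0.46, camera adjusted p = 2.73e-08) and oxidative stress genes (29 of 40 above 0, median 0.43, camera adjusted p = 0.00759) were higher with TGFb1 than in wild type. With an estimated correlation, adjusted p = 0.353 for each of the 3. No member passed over all genes; adjusted over each list alone, 1 ribosomal protein gene rose, Rpl27 (1.73, SE 0.41). Ndufc1 of respiratory complex I was at 0.71 (SE 0.22) and Hmox1 at 1.06 (SE 0.29). The identity list (camera adjusted p = 0.831), proliferation (0.985), chemokines (0.405), dendritic cell and monocyte markers (0.765) and the TGFb list (0.831) did not pass here.

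All 126 features called in beta6 null against wild type had a difference of opposite sign with TGFb1, and the median feature returned 0.75 of its difference (quartiles 0.60 and 0.94). Both comparisons share the beta6 null arrays, so part of this is given by chance. Xist is 1 of the 126 (2.69, then -2.67) and follows the same pattern. The labels give no sex, so a difference in the sex of the mice is not separated from a return with TGFb1. The return was computed on values whose spread was not made equal between arrays. The SD of an array ran from 0.841 to 2.008 in wild type, 0.916 to 1.998 in beta6 null and 0.845 to 1.402 with TGFb1. With equal spread the fall of Mmp12 with TGFb1 was smaller, and fewer features differed between the TGFb1 group and beta6 null. The share returned may therefore depend on the spread, which was not tested. When the beta6 null arrays were split 2 to 3 so that each comparison had its own, over 20 splits, a median of 94.9% of the called features moved back (70.7% to 100%) and the median share returned was 0.58 (0.13 to 0.78). For Mmp12 that share was 0.54, and 0.35 to 0.81 over the splits. Of the called features, 56 passed in both comparisons, 56 in opposite directions: 42 were lower in beta6 null and higher with TGFb1, among them Tpra1, Desi1, Fabp1, Oas3, Olr1, Id3, Il18, Skil and Klf10, and 14 were higher and then lower, among them Lat2, Mmp12, Rbp4, Marcks, Dpp4, Plbd1, Wfdc18, Hal, Igf2r and Fabp5. Independent lists of those sizes share 0.45 and 0.06 features, a figure that leaves out the shared beta6 null arrays. Simulated unchanged groups share 0.02 on average (at most 1), but with nothing changed few features can be called at all. Neither value tells how many real calls the shared arrays alone would put in both comparisons. With split arrays 0 to 33 were shared (median 13, of a median of 56 and 28.5 called). Over all features the 2 differences correlated at r = -0.645 across genes, which are not independent replicates, against -0.590 in simulated unchanged groups. The covariance was -0.41 against -0.26, a difference of -0.15, and with split arrays the covariance averaged -0.14 and the correlation -0.157 (-0.215 to -0.103).

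**Figure D3:**
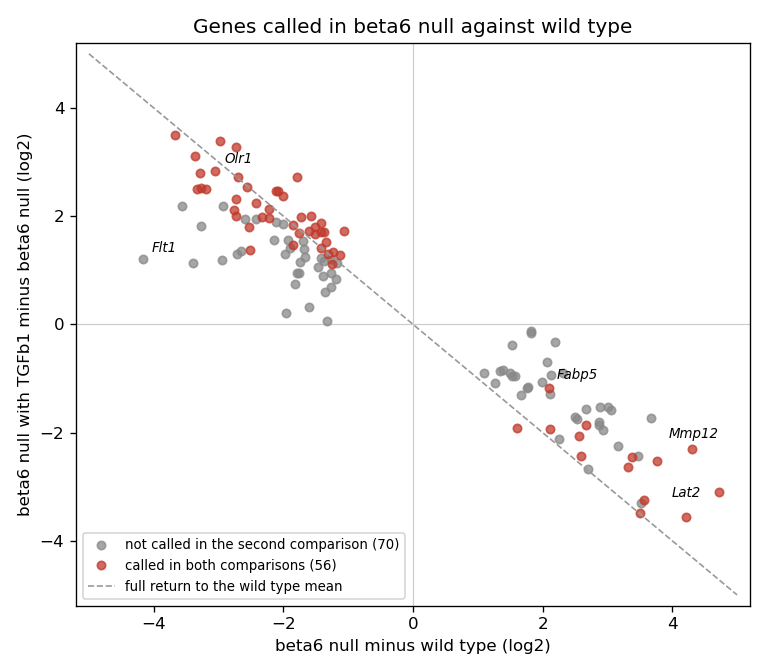
Each point is 1 of the 126 features called in beta6 null against wild type, with that difference on the horizontal axis and the difference of beta6 null with TGFb1 minus beta6 null on the vertical axis, both in log2. Features called in both comparisons (56) are red, the dashed line marks a full return to the wild type mean, and the beta6 null arrays enter both axes, which by itself tilts the cloud downwards.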

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

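The check for a sample far from its group was run on the genes described and on measures of the arrays, a choice of genes made after their values were seen. It took 219 groups of 4 or 5 arrays and asked whether the highest or lowest array lay apart from the rest by Dixon's test. It found 19, where chance gives about 1 in 20 groups, or about 11. A first run over all the genes the rule names and over list means had found 39 of 446 groups.

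Of the 19, 9 lay on wild type replicate 2 and 5 on beta6 null replicate 1, the 2 arrays with the widest values. On wild type replicate 2 the log2 ratio stood apart for C3ar1 (-1.204), Ctsk (-2.572), Flt1 (2.029), Tpra1 (1.963), Fabp1 (0.911), Id3 (-0.534), Eng (2.463), Ndufc1 (-0.281) and Tgfb1 (-4.838). On beta6 null replicate 1 it stood apart for Cd93 (0.202), Ly75 (-4.378), Pparg (-4.259), Ccnd2 (-3.683) and Axl (-2.898). The others were Krt19 on beta6 null replicate 3 (-4.245), Clec10a on wild type replicate 4 (-2.539), Desi1 on TGFb1 replicate 5 (-2.206), Tgfb1 on TGFb1 replicate 1 (-2.21) and Itgav on TGFb1 replicate 3 (0.653).

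The difference between beta6 null and wild type in 126 features was weighed against the 2 wide arrays and the sex of the mice, with both predictions written before the tests were run. Without the 2 arrays 100% of these features kept their sign and at least 0.5 of their difference. A call needs replicate arrays that lie close together, so this outcome was largely given by the choice of called features. More features passed in the fit without the 2 arrays than with them, so a difference between the groups does not need them. With the Xist level as a covariate 99.2% (124 of 125) kept their sign and at least 0.5 of their difference. The covariate is fitted to the spread within groups, and calls favour features with little of that spread. This outcome was therefore also largely given by the choice of features, and sex is not excluded. The median SE grew from 0.359 to 0.583 and 0 features passed by limma, so the influences of group and of sex on a single gene are not separated. Eif2s3y, a gene of the Y chromosome, averaged -0.77 in wild type, -1.795 in beta6 null and -0.48 with TGFb1. Kdm5d, also of the Y chromosome, had values on 5 beta6 null arrays (mean 0.122, highest 2.392), 2 wild type arrays (0.611) and 2 TGFb1 arrays (0.618), and the labels give no sex.

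The lower level of identity genes in beta6 null was weighed against a lower share of alveolar macrophages in the RNA, in a test written after the result was seen. Of the 24 members that did not pass over all genes, 22 (91.67%) had a 95% interval that excluded the mean fall of -2.66 of the 6 that fell, and 6 lay at or above 0. The split by which members passed puts the largest falls on 1 side and so largely fixes this outcome, and it decides nothing. Dendritic cell and monocyte markers moved against the identity list, higher in beta6 null (camera adjusted p = 0.0225, 12 of 15 above 0) and lower with TGFb1 (0.00928), and of the 6 genes that fell Flt1 and Krt19 are also on the endothelium and epithelium lists. A lower share of these cells, a change of their state and their replacement by other cells all stay open.

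Chance as the source of the counts was weighed by 100 splits of the arrays into groups of the same sizes, the real one among them, with predictions written before. For the features called in beta6 null against wild type (126), 1 of 100 splits, the real one, gave as many, and the highest other gave 1. A chance labelling of these arrays is therefore an unlikely source of the count. The labels do not say that the arrays hold separate animals, so a chance difference between animals, such as in sex, is not excluded. The same holds for the TGFb1 group against beta6 null (94, 1 of 100, highest other 2) and for the F test over the 3 groups (112, 1 of 100, highest other 2). For the TGFb1 group against wild type the real count is 0, so all 100 splits give as many by definition (highest other 1) and the splits decide nothing. For the lists chance cannot be excluded in beta6 null against wild type (4 lists, 7 of 100 splits, highest other 6) nor in the TGFb1 group against wild type (3 lists, 19 of 100, highest other 7). For the 10 lists in the TGFb1 group against beta6 null, 2 of 100 splits gave as many, fewer than predicted for chance. The highest other split gave 11, more than the real one, so chance is less likely there but not excluded. The count of 10 falls to 5 without beta6 null replicate 4. It falls to 6 without wild type replicate 1, beta6 null replicate 5 or TGFb1 replicate 3, and these lower counts were not set against splits.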

How the results depend on the processing

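Equal spread of the arrays, leaving out the 2 widest arrays and the Xist covariate were chosen after the data were seen. Of the values tested again for the comparisons, 184 kept their direction and side of the threshold (counts: within 1.5 times), 59 moved and 7 lost their call. Of those for named genes 453 kept both, 77 lost and 26 gained a call and 14 turned their sign. The number of arrays and of missing spots limits what can be detected. No paired analysis was possible because the labels carry no replicate number or pair. Unless said otherwise the cause was not tested.

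Against the 126, 94, 0 and 112 features of beta6 null against wild type, TGFb1 against beta6 null, TGFb1 against wild type and any group, the counts were as follows. Quantile normalization gave 76, 15 and, for any group, 70. Equal spread gave 61, 11 and, for any group, 55. Array weights gave 422, 620 and 1 (TGFb1 against wild type). The title suffix as a block gave 64, 43 and, for any group, 57. Without the 2 arrays numbered apart they were 78, 30 and, for any group, 63, and without the 2 widest 190, 321 and, for any group, 224. The Xist covariate gave 0, 0 and, for any group, 0. In the first 2 the differences of called features kept a median of 0.973 and 0.970 of their size while the median SE grew from 0.359 to 0.583 and from 0.336 to 0.543. The 10 arrays of the 2 groups alone gave 41 for beta6 null and 1 for TGFb1 against wild type, and features on all 15 arrays gave 220 for TGFb1 against beta6 null. By construction adjusted p under 0.01 gave 49 and 23, and under 0.10 gave 202 and 294. Leaving out 1 array gave 64 to 154, 23 to 318, 0 to 1 and 56 to 222.

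The rise of Mmp12 in beta6 null was 4.07 with the Xist covariate (adjusted p = 0.110, over all alternatives 3.69e-05 to 0.110), and 3.98 to 4.50 leaving out 1 array. Its fall with TGFb1 was -2.05 by quantile normalization, -2.20 without the 2 arrays numbered apart, -1.22 with equal spread and -2.09 with the Xist covariate, and -2.50 to -1.98 leaving out 1 array.

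Lists past the threshold numbered 4, 10 and 3, and 0, 0 and 0 with an estimated correlation. They were 2 in beta6 null with the Xist covariate and 0 in TGFb1 against wild type by fry. Leaving out 1 array gave 3 to 8 (8 without beta6 null replicate 4), 5 to 12 (5 without beta6 null replicate 4, 6 each without wild type replicate 1, beta6 null replicate 5 and TGFb1 replicate 3) and 2 to 4. The correlation of the return was -0.157 with split arrays and -0.950 among called features alone. The value of -0.950 is largely given by the choice of called features and by the shared beta6 null arrays.

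Some values that never passed turned their sign. Tgfb1 in beta6 null against wild type was -0.406 without the 2 widest arrays and ran from -0.7255 to 0.771 leaving out 1 array. In TGFb1 against beta6 null, leaving out 1 array gave -0.5245 to 0.426 for Tgfb1, -0.544 to 0.03645 for Itgb6 and -0.460 to 0.103 for Itgav. Array weights gave 0.0689 for Itgb6 and 0.405 for Itgb5, and Itgav was 0.103 without the 2 widest. In TGFb1 against wild type, Tgfb1 was -0.730 without the 2 widest, -0.445 with array weights and -0.2775 by quantile normalization. Leaving out 1 array gave -0.730 to 0.627 for Tgfb1, -0.1525 to 0.428 for Itgb6 and -0.0114 to 0.677 for Itgav.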

Other observations

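Lists not yet described held few calls in beta6 null against wild type. Oas3 fell among 31 interferon-induced genes (camera adjusted p = 0.582), Egr2 fell among 34 immediate early and heat shock genes (0.380) and Gas6 rose among 14 genes of coagulation (0.239). No member passed among 17 integrins, 18 genes of MHC class I, 27 of cholesterol and fatty acid synthesis, 40 of oxidative stress, 64 ribosomal proteins or 69 of oxidative phosphorylation, with camera adjusted p from 0.107 to 0.904. In the TGFb1 group against beta6 null, 1 of 27 genes of cholesterol and fatty acid synthesis rose, Stard4, singled out after its value was seen (2.23, adjusted p = 0.00492), and the list did not pass camera (adjusted p = 0.0501) but did pass fry (0.0448). Fry alone also passed the lists of lipid uptake, storage and efflux, higher (0.0275, camera 0.250), and of B and plasma cell markers, lower (0.0271, camera 0.0501).

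Genes that lie beside Itgb6 on its chromosome were called more often than others in beta6 null against wild type. Of the 25 protein-coding genes on each side, 29 were tested and 3 called (10.3%): Dpp4 (3.56), Ly75 (-2.72) and Cd302 (-1.60, singled out after its value was seen). Of the other genes 110 of 10782 (1.02%) were called (Fisher's exact p = 0.00333, chosen after the calls were seen). With TGFb1 4 neighbours differed from beta6 null, Cytip (1.60), Cd302 (1.73), Dpp4 (-3.25) and Gca (2.603).

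A hypothesis, written after the result was seen, was that DNA of another strain carried along with the disrupted gene set these levels. By itself it would leave both groups that lack beta6 alike, unless TGFb1 also acts on these genes. The difference of the TGFb1 group from wild type was a median of 0.0880 of that of beta6 null for the 3 called genes (-0.0776 to 0.521). Dpp4 (0.0880) and Cd302 (-0.0776) returned, which strain DNA by itself would not give if both groups carry the same DNA there. That they do was assumed and not tested, and an effect of TGFb1 on these genes was not set apart. The 3 genes were also chosen through the beta6 null arrays that enter the return. The return therefore does not exclude the hypothesis. Ly75 kept 0.521 of its difference, and its return with TGFb1 did not pass by limma (adjusted p = 0.104). The DNA of the mice was not analysed here, and with 3 genes a part of the effect for any 1 of them is not excluded.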
